A study of Mus musculus with 36 samples.

How the data were processed

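RNA from the livers of 36 female mice, 4 in each of 9 groups, was measured on Affymetrix expression arrays, 1 array per mouse. Per the labels, the mice were 6 to 8 weeks old and were fasted for 4 to 5 hours before dissection, a liver piece of 0.5 cubic centimetres was excised, and biotin-labelled cRNA was made from 3 micrograms of total RNA. The groups were heterozygotes of 4 mutant lines (Pax3 Sp2H, Lrp6 Cd, Apob tm1Unc and Vangl2 Lp), curly tail (ct) mice, and 4 wild type control groups (B6, Cd, CBA and Lp). The B6 group was the control of both the Pax3 and the Apob line.

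The authors computed each probe set's signal with MAS5, whose version is not stated, and the deposited unit is linear signal intensity. Each array was scaled by the authors to a trimmed mean of 500 (the 2% of probe sets at each end left out), as computed here from the values. MAS5 signal is not quantile normalized and is noisy near background. Signals ran from 0.0712 to 111483. The table held 45101 probe sets, of which 64 were array controls. A probe table of the platform paired 34945 probe sets with 1 gene symbol each and 932 with several, and left 9160 unnamed here. The Entrez IDs of 34754 of the single-symbol probe sets were found in the RefSeq table of the mouse assembly GRCm38.p6, which was used for current symbols and for gene order.

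Values were analysed as log2 of the signal plus 23.068, the 20th percentile of all signals. A probe set was tested where its mean log2 value passed 6.4057, the 40th percentile, which corresponds to a signal of 61.717. The probe set with the highest mean stood for each gene, which left 13188 genes of 18193 symbols. A linear model with 1 mean per group was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3, with a variance trend on intensity. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. A log2 difference is given as mutant minus control ± its standard error from this model, and a signal as the group's mean ± SD over 4 arrays. With 4 arrays per group, the number of arrays limits the precision.

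Comparisons were each mutant group against its control, the mean of the 2 lines called responsive to dietary folic acid minus the mean of the 3 called resistant, the mean effect of the 5 lines, differences among the 5 effects (moderated F test) and differences among the 4 control groups (moderated F test). In total 29 gene lists for liver metabolism, stress, signalling and cell types were fixed, of which 27 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01 between genes, then with an estimated correlation, and with fry, all adjusted over the lists of a comparison. Genes were also adjusted over the list alone.

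The comparisons, tests, thresholds, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took the mutated gene, the 10 largest increases and the 10 largest decreases among called genes whose 4 mutant values all lay above or all lay below the 4 control values, and up to 4 called members of each list that passed its test or held 3 called members. Where fewer than 10 genes were called, the 5 genes with the smallest p in each direction were taken and are given as values, and for comparisons across lines the 5 with the smallest p.

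The procedure was tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold added to noise. This noise had the spread of each gene on the arrays and was drawn independently for each gene and array. The procedure called 57% of the former and 98% of the latter, with 6 false calls, and it called 0 of 20 unchanged lists. As the simulated genes were uncorrelated, the last result does not show how often camera passes unchanged lists of correlated genes.

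Alternatives were quantile normalization, centring of each array on its median, 2 other offsets, no filter and a stricter filter, no variance trend, array weights, fits to the compared arrays alone, all probe sets, probe sets without shared or mixed targets, a block for the replicate number, and the removal of each array in turn. Fits without CBA replicate 4, and without it and ct replicate 3, were added after the data were seen. Other groupings of the same arrays were counted as well. Nothing among the 36 arrays was left out of the analysis. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.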

Results

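Liver gene expression was measured in 5 mouse lines that carry mutations causing neural tube defects, and in their wild type controls. The lines were splotch (Pax3 Sp2H, a mutation of a transcription factor of the dorsal neural tube), crooked tail (Lrp6 Cd, a Wnt co-receptor), Apob tm1Unc (apolipoprotein B, the structural protein of very low density lipoproteins), curly tail (ct, a hypomorphic allele of the epithelial transcription factor Grhl3) and loop tail (Vangl2 Lp, a planar cell polarity protein). The labels describe the Pax3 and Lrp6 lines as responsive to folic acid in the diet and the Apob, ct and Vangl2 lines as resistant to it. Each of the 9 groups held 4 female mice and 13188 genes were tested on the 36 arrays. The ct mice came from a random-bred closed colony, and their controls were CBA mice, so this comparison spans different stocks.

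The ratio of the 3' to the 5' control signal of GAPDH, a measure of RNA quality, lay between 0.729 and 0.956 on 34 arrays and was 52.5 on CBA replicate 4 and 1.72 on ct replicate 3. On the same 34 arrays the ratio of actin ran from 1.63 to 2.93 and that of pyruvate carboxylase from 2.99 (Apob replicate 4) to 26.6 (B6 replicate 3). The pyruvate carboxylase ratio was lower on every Apob array (2.99 to 5.21) than on every B6 array (5.99 to 26.6). The median correlation of an array with the other arrays was 0.845 for CBA replicate 4 and 0.901 for ct replicate 3, and at least 0.927 for the other 34.

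**Figure D1:**
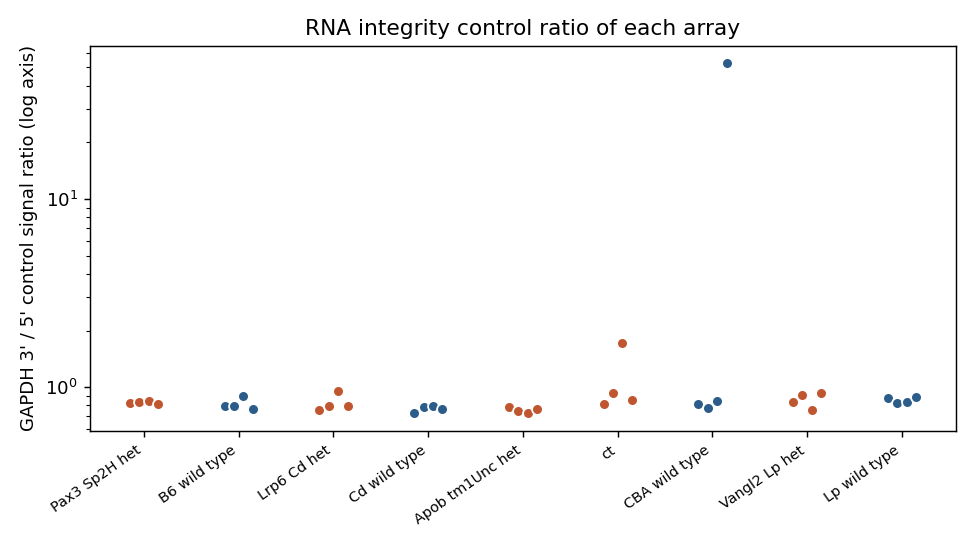
Ratio of the 3' to the 5' GAPDH control signal (log axis, no unit) of each of the 36 arrays, by group, with mutants in orange and controls in blue. CBA replicate 4 at 52.5 and ct replicate 3 at 1.72 lie above all others, which range from 0.729 to 0.956.

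In Apob heterozygotes, the Apob transcript itself fell. Values of female-biased and cholesterol synthesis genes leaned lower and those of male-biased genes higher as lists, with 1 of 10, 0 of 20 and 0 of 7 members called over all genes by limma, and none of these lists passed camera with an estimated correlation (adjusted p = 0.0538, 0.431 and 0.413). Of 13188 genes, 71 were called, 31 higher and 40 lower, and 47 of them differed by more than 2-fold. The Apob probe set read a signal of 7849 ± 4604 (SD, n = 4) in heterozygotes and 23830 ± 4452 in B6 wild type mice. That is a log2 difference of -1.82 ± 0.42 (limma adjusted p = 0.0333), and a second Apob probe set gave -2.43 ± 0.59. The call was lost in 5 of 22 refits, those without B6 replicate 1, 2 or 3 or Apob replicate 1 or 3 (adjusted p from 0.00194 to 0.195 over the 22). Among called genes whose groups did not overlap, the largest decrease was that of Sult2a2, a sulfotransferase of bile acids and steroids, which read 401.5 ± 330.7 against 6672 ± 2247 (log2 -4.29 ± 0.72, adjusted p = 0.00176).

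Pparg, a nuclear receptor of lipid storage, fell by 1.91 on the log2 scale (adjusted p = 0.000715), from a signal of 205.3 to 37.92, a level near background at which the size of the difference depends on the offset. Mfsd2a, a transporter of lysophosphatidylcholine, fell by 1.58, and Fads1, a fatty acid desaturase, fell by 0.91 with a second probe set at -1.52. Ccnd1, which encodes the G1 cyclin D1, fell by 2.11, and its other probe sets gave -1.58 and -1.79. The organic anion transporters Slco1a4 (-1.64) and Slc22a27 (-1.90) fell, as did the semaphorin Sema3f (-2.02). Erdr1 gave -3.45 and Csnk2a1, a catalytic subunit of casein kinase 2, gave -1.73, but another Erdr1 probe set gave -0.35 and 4 other Csnk2a1 probe sets gave values from -0.43 to 0.18. Slco1a4 lost its call in 10 of 22 refits, among them those without any 1 of the Apob arrays or of B6 replicates 1, 2 and 3, and Fads1 in 8 of 22, among them those without any 1 of replicates 1, 2 and 3 of either group. Sema3f and Slc22a27 lost it in 3 of 21, both without B6 replicate 1 or Apob replicate 3 and Sema3f also without Apob replicate 1. Mfsd2a lost it without Apob replicate 2, Csnk2a1 without B6 replicate 3 and Erdr1 without probe sets of shared targets.

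The largest increases among such genes were those of Pidd1 (log2 1.88), Sh3d19 (1.80), the RNA polymerase III subunit Polr3k (1.79), the cystine transporter subunit Slc3a1 (1.71), Hectd2 (1.68) and the axonemal dynein Dnah5 (1.67). The arginine methyltransferase Prmt1 rose by 1.53 ± 0.28 (adjusted p = 0.00419), from 198.3 ± 29.58 to 616.6 ± 70.28. Kcnmb2 (1.42), Rdx (1.23) and Ociad2 (1.19) also rose, and a second Ociad2 probe set gave 1.15. Other probe sets of Sh3d19 gave 2.06 and 0.05, and those of Rdx gave -0.45 and 0.12. The 3 other Polr3k probe sets gave 0.31 to 0.51, and that of Kcnmb2 gave 0.06. The B6 signals of Dnah5 (37.25), Kcnmb2 (46.54) and Hectd2 (61.55) were near background, so that the size of these differences depends on the offset. It ran from 1.13 to 2.11 for Dnah5 and from 1.26 to 1.97 for Hectd2, and was 0.96 for Kcnmb2 at the higher offset. At the lower offset Kcnmb2 gave 0.07, close to the 0.06 of its other probe set. The probe set of each gene was chosen anew under each offset, so this drop cannot be put down to the offset alone.

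Most of these increases depended on single arrays. Polr3k lost its call in 12 of 22 refits and Slc3a1 in 8 of 22, in each case among them those without any 1 array of the comparison other than Apob replicate 4. Pidd1 lost it in 9 of 21, among them those without any 1 array other than B6 replicate 4, and Kcnmb2 in 9 of 21, among them those without B6 replicate 3 or 4 or Apob replicate 1, 2 or 3. Ociad2 lost it in 5 of 22 (without B6 replicate 2 or 3 or Apob replicate 1 or 3, and after median centring), Dnah5 in 4 of 21 (without B6 replicate 1, 2 or 3 or Apob replicate 2), Hectd2 without B6 replicate 3, and Sh3d19 without probe sets of shared targets.

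All 10 tested female-biased genes were lower in Apob heterozygotes (median log2 -1.45). Of these, 1 was called over all genes, Sult3a1 (-4.66 ± 1.12, adjusted p = 0.0416). It lost the call in 10 of 22 refits (adjusted p from 0.00304 to 0.201), among them those without any 1 of the B6 arrays and those without Apob replicate 1 (0.161), 3 (0.201) or 4 (0.0827). In all, 6 were lower when adjusted over the list alone, namely Sult3a1, Cyp3a16 (-3.29), Cyp2b13 (-2.59), Hao2 (-2.10), Cyp3a44 (-1.80) and Cyp17a1 (-1.03). The list passed camera (adjusted p = 3.81e-08) and fry (adjusted p = 0.0162), with adjusted p = 0.0538 with an estimated correlation. All 7 male-biased genes had positive values (median 0.83), among them Hsd3b5 (2.27 ± 0.95) and Elovl3 (1.21 ± 0.47), and 0 were called over all genes or adjusted over the list alone by limma, with 3 at an unadjusted p below 0.05. The male-biased list passed camera (adjusted p = 0.0052, and adjusted p = 0.413 with an estimated correlation). The shifts were unequal between mice, as the mean of the female-biased genes relative to B6 was -2.01, -0.28, -3.17 and -1.86 on the 4 Apob arrays.

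**Figure D2:**
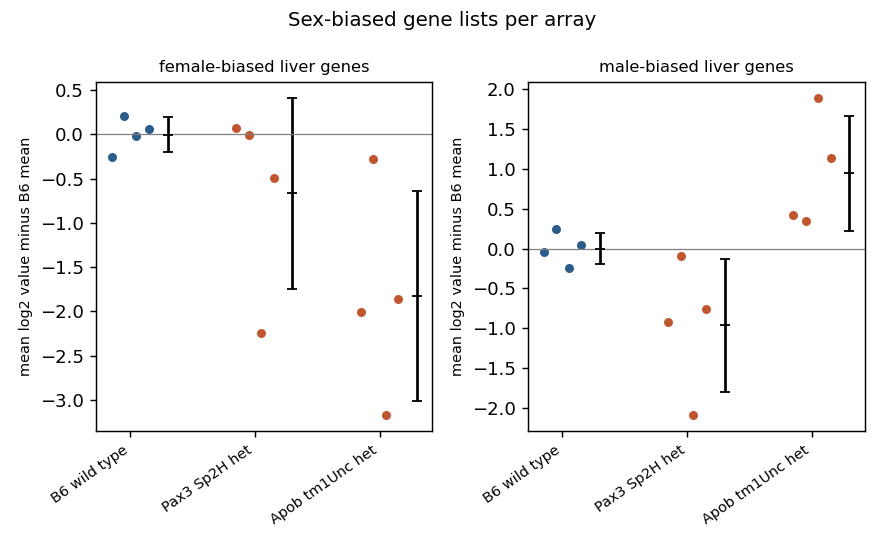
Mean log2 value of the 10 female-biased and the 7 male-biased liver genes on each array, minus the B6 mean (y axis, log2 units), with bars at the group mean ± SD (n = 4). On the female-biased list the Apob arrays lie between -3.17 and -0.28, and Pax3 replicate 3 lies at -2.24.

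Cholesterol synthesis genes were lower in Apob heterozygotes in 19 of 20 cases (median -0.62, camera adjusted p = 6.69e-06, and adjusted p = 0.431 with an estimated correlation). None was called over all genes, with 6 at an unadjusted p below 0.05, and 2 were lower when adjusted over the list alone, Stard4 (-0.91) and Hmgcs1 (-1.15, the enzyme before HMG-CoA reductase). Fatty acid oxidation genes had a median of -0.32, with 27 of 30 negative (adjusted p = 0.000123, and 0.431 with an estimated correlation). Fatty acid synthesis genes had a median of -0.29 with Fads1 called (adjusted p = 0.0117, and 0.667 with an estimated correlation). Lipoprotein genes (median -0.19, with Apob called) and glucose and amino acid genes (median -0.23) passed camera with adjusted p = 0.00815 and 0.0117, had adjusted p = 0.162 and 0.413 with an estimated correlation. After quantile normalization neither passed camera (adjusted p = 0.0902 and 0.0665), and after median centring both did (0.00977 and 0.0227).

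The 4 heterozygote values lay all above or all below the 4 control values in 1238 of the 13188 genes, where chance gives 2.86%, and 67 of the 71 called genes were among them. Single arrays moved the count: it was 24, 30 and 40 without Apob replicates 3, 1 and 2, and 40, 34 and 29 without B6 replicates 1, 2 and 3. Median centring of the arrays left 40 calls, 6 of them higher. Without CBA replicate 4 and ct replicate 3, arrays of another comparison in the same fit, 324 genes were called, including all 71.

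In ct mice, 4 of 24 fatty acid synthesis and 4 of 20 cholesterol synthesis genes fell against CBA controls, and 8 of 26 acute phase, 6 of 12 Kupffer cell and 3 of 18 lipoprotein genes rose. These 5 lists passed camera with the preset correlation and none passed with an estimated one, and 0 of 26 acute phase and 0 of 12 Kupffer cell genes were called by limma without ct replicate 3 and CBA replicate 4, the arrays of doubtful RNA. In all, 877 genes were called, 448 higher and 429 lower, and 385 differed by more than 2-fold. Among called genes whose groups did not overlap, the largest increases were Gm7969 (log2 4.04), the zinc finger gene Zfp874a (3.84), the aldehyde oxidase Aox3 (3.25), the nicotinamide methyltransferase Nnmt (3.20), Slc25a48 (2.78), Tmem51 (2.65), the defensin Defb1 (2.52), Rnf41 (2.51), the elastase Cela2a (2.44) and Acpp (2.41). Other probe sets gave 0.81 and 0.90 for Rnf41, 3.31 for Gm7969 and 2.31 for Defb1. Aox3 read 3470 ± 1790 (SD, n = 4) in ct mice and 338.8 ± 174.5 in CBA mice, and Nnmt read 23230 ± 16620 against 2209 ± 623. The CBA signals of Slc25a48 (10.3), Acpp (29.35), Cela2a (35.03) and Gm7969 (38.73) were near background, so the size and rank of these differences depend on the offset, from 1.81 to 3.76, 1.7 to 3.09, 1.77 to 3.02 and 3.31 to 4.51.

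The largest decrease was at an Mff probe set (log2 -7.03), from 7302 ± 3796 in CBA to 33.25 ± 24.87 in ct mice, near background, while other probe sets of Mff, which encodes a mitochondrial fission factor, gave -3.22 and 0.14. Tmie (-4.10), 1700001C19Rik (-3.95), Elobl (-3.30), Gm4951 (-3.17), Lrba (-3.10), the succinate receptor Sucnr1 (-2.85), Klf12 (-2.82), the acyl-CoA synthetase Acsl4 (-2.37) and Zfp979 (-2.33) followed. Both other probe sets of Tmie, Klf12 and Acsl4 were negative too. The ct signals of Zfp979 (15.87) and Elobl (44.98 ± 59.03) were near background too, and at the higher offset Zfp979 gave -1.5 and Elobl -2.48. That of Tmie (63.95 ± 89.9) lay just above the signal of the filter, 61.717. Without CBA replicate 4 and ct replicate 3, these 20 genes remained called except Cela2a (1.61 ± 0.47) and Acpp (1.99 ± 0.57).

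Of 24 fatty acid and triglyceride synthesis genes, 4 fell and 1 rose. Srebf1, the transcription factor that drives this pathway, fell by 1.81 ± 0.35 on the log2 scale, ATP citrate lyase Acly fell by 1.79 ± 0.39, the acetyl-CoA synthetase Acss2 by 2.19 ± 0.57 and the acyltransferase Gpam by 1.15 ± 0.21. Other probe sets of Acly gave -1.56, -0.63 and 0.13. The lipid droplet gene Plin2 rose (0.71 ± 0.19). Adjusted over the list alone, 9 were lower and 3 higher. The list passed camera (median -0.77, adjusted p = 0.0135, and 0.613 with an estimated correlation), and Srebf1, Acly and Gpam remained called without the arrays of doubtful RNA.

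Of 20 cholesterol synthesis genes, 4 fell, Hmgcs1 (-1.45), Insig1 (-1.22), the squalene synthase Fdft1 (-1.06) and Lss (-0.99), and 4 were lower adjusted over the list alone. This list had a median of -0.70 (camera adjusted p = 0.000413, and 0.613 with an estimated correlation). Without the same 2 arrays these 4 kept their sign and lost the call, as for Hmgcs1 (-1.07 ± 0.37) and Fdft1 (-0.70 ± 0.22). With all arrays another Fdft1 probe set gave -0.32 ± 0.42, and those of Hmgcs1 and Lss gave -1.63 to -0.66. On ct replicate 3 and CBA replicate 4, the mean of the list relative to CBA was -1.37 and -0.90, against -0.48 to -0.28 on the other ct arrays.

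**Figure D3:**
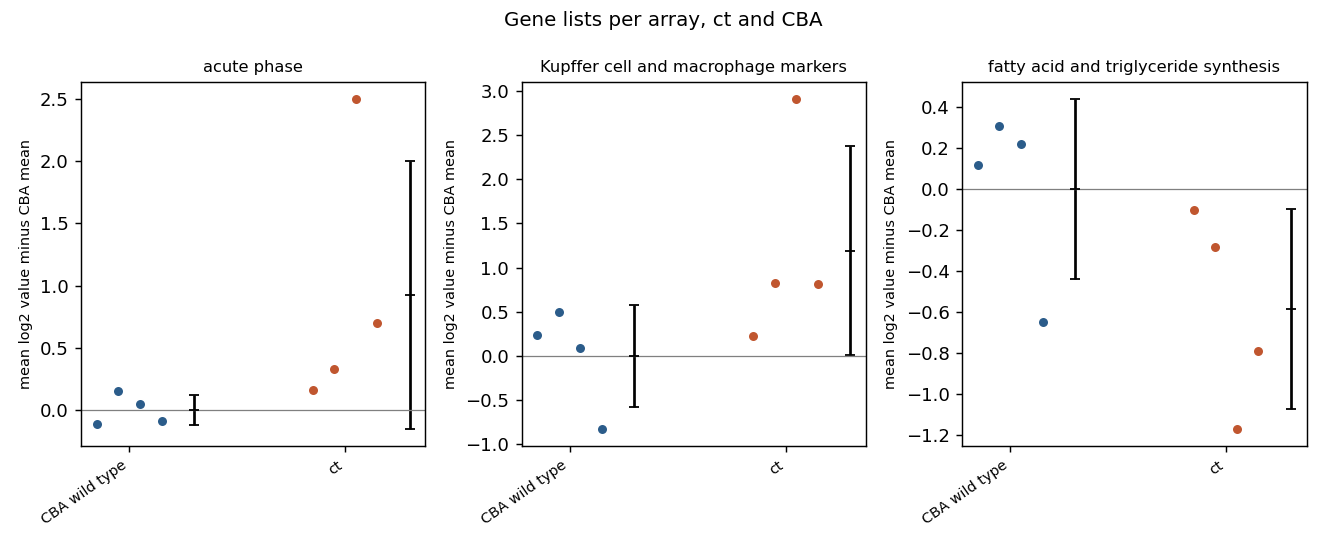
Mean log2 value of the acute phase, Kupffer cell and fatty acid synthesis lists on each ct and CBA array, minus the CBA mean (y axis, log2 units), with bars at the group mean ± SD (n = 4). The acute phase mean of ct replicate 3 lies at 2.50 and those of the other ct arrays between 0.16 and 0.70.

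Acute phase genes, which the liver raises during inflammation, rose in 8 of 26 cases in ct mice, and 16 of 26 adjusted over the list alone. They included haptoglobin Hp (0.96), Lbp (1.34), Serpina3n (1.69), hemopexin Hpx (0.88), Saa1 (2.22), Saa2 (3.09), Orm2 (2.24) and Itih3 (0.69). The list passed camera (median 0.68, adjusted p = 2.39e-07, and 0.613 with an estimated correlation) and fry (adjusted p = 0.0276). Kupffer cell and macrophage markers rose in 6 of 12 cases, and 9 adjusted over the list alone, among them Lyz2 (1.78), the scavenger receptor Marco (2.79), C1qb (1.56) and Clec4f (1.24), with a median of 1.27 (camera adjusted p = 6.23e-06, and 0.613 with an estimated correlation). Marco read 931.8 ± 1646 against 14.55 ± 5.38, a control level near background, and gave 2.08 to 3.46 by offset. On the ct and CBA arrays, ct replicate 3 had the highest acute phase mean (2.50) and Kupffer mean (2.91), and CBA replicate 4 the lowest Kupffer mean (-0.83). Without those 2 arrays 0 of 26 and 0 of 12 were called by limma, the medians were 0.34 and 0.27, and Hp (0.44 ± 0.13) and Lyz2 (1.06 ± 0.30) kept their sign.

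Lipoprotein genes rose in 3 of 18 cases, and 7 were higher and 1 lower adjusted over the list alone. Apoa4 rose by 1.01 ± 0.20 and remained called without the 2 arrays (1.13 ± 0.23), while Apoe (1.18) and Lcat (1.17) did not. The list passed camera and fry (adjusted p = 0.0197 and 0.00112), had adjusted p = 0.547 with an estimated correlation, and had camera adjusted p = 0.111 after quantile normalization and 0.0287 after median centring. Among PPAR alpha targets, Cyp4a14 rose by 2.66 ± 0.57 (3.56 ± 0.55 without the 2 arrays), and Pex11a (1.20) and Angptl4 (1.04) rose with all arrays. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.20 and Akr1d1 by 1.18, and the sterol sensor Nr1h3 rose by 0.84, and none of these 3 remained called without the 2 arrays. A second probe set gave -1.15 for Cyp7a1 and 0.21 for Akr1d1. The clock genes Per3 (-1.14) and Dbp (-1.20) fell and Nfil3 rose (1.46), and of these Per3 remained called without the 2 arrays. Other probe sets of Per3 gave -0.93, -0.30, -0.06 and 0.21, and that of Dbp gave -0.45.

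Genes of methyl group metabolism moved both ways in ct mice. Of 23 in the methionine list, Nnmt, Gnmt (0.59, a glycine methyltransferase) and Ahcy (0.48, S-adenosylhomocysteine hydrolase) rose and Mat2b fell (-0.72), and the list did not pass camera (adjusted p = 0.34). Ldha rose (0.83), and the glycogen phosphorylase Pygl (-0.71) and the glucose transporter Slc2a2 (-0.83) fell. Among ribosomal protein genes Rpl14 fell (-1.38) and Rps14 (1.34) and Rps3 (0.79) rose, the last with other probe sets at -0.18 and 0.07. Without the 2 arrays, Nnmt (2.63) and Rpl14 (-1.31) remained called in this group. Grhl3, the mutated gene, was near background, with 41.08 ± 25.29 in ct and 57.63 ± 13.12 in CBA livers (n = 4), and lay below the filter. In a fit without the filter its log2 difference was -0.42 ± 0.37.

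The groups did not overlap in 912 of the 13188 genes, where chance gives 2.86%, and 532 of the 877 called genes were among them. The count was 414 without CBA replicate 4, 363 without ct replicate 3 and 236 without both, of which 183 were among the 877. It was also 575 without ct replicate 2, and 1438, 1399 and 1335 without ct replicate 1, CBA replicate 2 and CBA replicate 3, and median centring gave 426 higher of 643. A fit to the 8 compared arrays alone called 38 genes, all among the 877. None of the 20 genes with the largest changes lost its call without any 1 array. Of the 37 other named genes, 26 lost it without ct replicate 3, 21 without CBA replicate 4, 8 without ct replicate 2, 4 without ct replicate 4, 3 without CBA replicate 1 or 2, and 2 without ct replicate 1 or CBA replicate 3, and all 37 lost it in the fit to the 8 arrays. Camera passed 5 of 27 lists, with 9 and 8 without ct replicates 1 and 4, and 3 without CBA replicate 1 or 2.

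Between Vangl2 Lp heterozygotes and their controls 4 genes differed, all higher in the heterozygotes, and for Ciart, Alas1 and Coq10b the control group was the lowest of the 9 groups. Alas1, the rate-limiting enzyme of heme synthesis, read 12780 ± 6455 in heterozygotes and 2140 ± 966.4 in Lp wild type mice (SD, n = 4), a log2 difference of 2.52 ± 0.40 (limma adjusted p = 0.00347), with a second probe set at 1.45 ± 0.53. Ciart, a circadian repressor, read 450.9 ± 309.3 against 22.8 ± 12.03 (adjusted p = 0.00347), and as the control mean lay at background its log2 difference depended on the offset, from 2.33 to 3.85. Coq10b, a coenzyme Q binding protein, differed by 1.67 ± 0.30 with a second probe set at 1.70, and the pentraxin Apcs, serum amyloid P, by 1.25 ± 0.24.

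The Lp wild type arrays read 15.09 to 40.6 for Ciart, below every array of the other 8 groups, whose lowest was 46.13. For Alas1 they read 1340 to 3480, against 5991 to 20890 in Lp heterozygotes, 11670 to 20140 in B6 and 9010 to 16630 in CBA mice, while single arrays of the Apob (2922) and Cd wild type (3073) groups lay within their range. For Coq10b they read 330.5 to 873.2, against 2012 to 2754 in B6 and 1374 to 2768 in CBA mice. Apcs was not of this kind, at 9202 ± 1638 in Lp wild type, 9391 ± 1506 in Pax3 and 12360 ± 2879 in B6 mice, against 21870 ± 4161 in Lp heterozygotes.

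Clock genes were higher in Lp heterozygotes than in Lp wild type mice in 12 of 17 cases (median 0.39, camera adjusted p = 1.89e-05, and 0.0898 with an estimated correlation). Adjusted over the list alone, 6 were higher, Ciart, Usp2 (1.47 ± 0.45), Dbp (1.20 ± 0.35), Per3 (1.18 ± 0.31), Wee1 (1.06 ± 0.28) and Nr1d2 (0.59 ± 0.22). Arntl and Nfil3, which peak at other times of day than these, had values of -0.63 ± 0.27 and -1.0 ± 0.41 and were not called. The Per3 signal was 322.4 to 762.5 on the heterozygote arrays and 166.5 to 225.9 on the controls, against 278.9 to 578 in B6 and 298.4 to 990.9 in CBA mice, and Dbp was 4903 to 7739 and 1129 to 5434, against 4777 to 8715 in B6 mice. The heterozygotes thus lay within the range of the other groups and the Lp wild type group was low, as the Apob group was for Per3 (194.3 to 377.2). The lowest ct signals, 1369 for Dbp and 132.9 for Per3, were those of ct replicate 3, an array of doubtful RNA. The other ct arrays read 4777 to 6347 for Dbp and 297.2 to 350.1 for Per3, within the B6 range. The times of dissection were not in the labels.

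**Figure D4:**
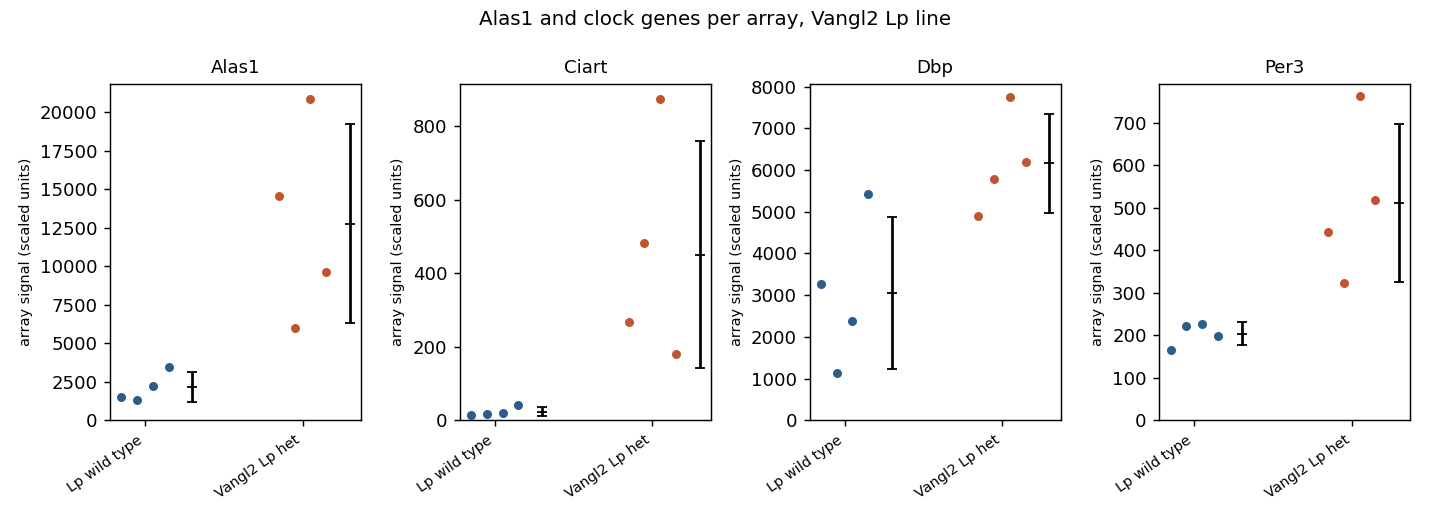
Signal of Alas1, Ciart, Dbp and Per3 (y axes, scaled MAS5 units) on each Lp array, with bars at the group mean ± SD (n = 4). For Alas1, Ciart and Per3 every heterozygote array lies above every control array, as for Ciart with 180.2 as the lowest heterozygote and 40.6 as the highest control.

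Cell cycle genes had a median of 0.39 in Lp heterozygotes (camera adjusted p = 0.000284, and 0.637 with an estimated correlation), and Cdk1 (1.39) and the ribonucleotide reductase subunit Rrm2 (0.68) were higher adjusted over the list alone. Oxidative phosphorylation, ribosomal protein, acute phase and lipoprotein genes had medians of 0.22, 0.26, 0.26 and 0.17 and passed camera. After quantile normalization their medians were 0.08, 0.11, 0.03 and 0.01 and none of the 4 lists passed (adjusted p from 0.101 to 0.959), while after median centring 3 passed and the lipoprotein list did not (0.0558), and with an estimated correlation they had adjusted p from 0.451 to 0.681. Genes outside the threshold with the smallest p were 1810055G02Rik (1.43, adjusted p = 0.051), C730049O14Rik (-1.07), the tight junction gene Cgn (-0.92), Lasp1 (-1.13), Ypel2 (-1.27) and Pwwp3a (-0.78). Vangl2 itself did not differ (0.35 ± 0.29), and its other probe sets gave -0.01 and 0.04.

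The groups did not overlap in 754 of the 13188 genes, where chance gives 2.86%, and all 4 called genes were among them. An unadjusted p below 0.05 was found for 933 genes. The count was 0 without heterozygote replicate 3, 2 without heterozygote replicate 2 or control replicate 2, and 9 without control replicate 1. It was 28 without CBA replicate 4 and ct replicate 3, including these 4. Apcs lost its call in 6 of 22 refits, those without heterozygote or control replicate 2, 3 or 4, Coq10b in 4, among them those without heterozygote replicate 2 or 3 or control replicate 2, and Alas1 and Ciart in 1, without heterozygote replicate 3.

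In Pax3 Sp2H heterozygotes no gene was called by limma, with 702 of 13188 at an unadjusted p below 0.05 where chance gives 659, and the smallest adjusted p was 0.263. The groups did not overlap in 710 genes, where chance gives 2.86% of the 13188. The smallest p values belonged to Fscn3 (1.5 ± 0.31), Fbxo42 (1.51), Tubb2a (1.08), Cog7 (0.96) and Rfc4 (0.79) among higher genes. Among lower genes they belonged to Fv1 (-1.62 ± 0.34), Lifr, a cytokine receptor (-1.39), Tspan32 (-1.30), Enho (-1.16) and Zfp862-ps (-1.07). Other probe sets of Fbxo42 and Lifr gave values between -0.06 and 0.26. Fscn3 (19.53 in B6), Fv1 (17.92 in heterozygotes) and Zfp862-ps (49.96 in heterozygotes) were near background in 1 group and ran from 0.89 to 2.20, -2.26 to -0.99 and -1.32 to -0.73 by offset. Pax3 was close to background in liver, at 35.4 ± 47.73 against 53.86 ± 32.43.

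As groups, fatty acid oxidation genes were lower in Pax3 heterozygotes, with 27 of 30 negative (median -0.35, camera adjusted p = 1.04e-06, and 0.384 with an estimated correlation). Examples are Vnn1 (-0.95 ± 0.30), Ech1 (-0.57), Decr1 (-0.43) and Hadhb (-0.40). All 7 male-biased genes were negative (median -0.82, adjusted p = 0.000369, and 0.278 with an estimated correlation), and Slco1a1 (-2.53 ± 0.73) and Ugt2b38 (-1.14 ± 0.39) were lower adjusted over the list alone. Their mean relative to B6 was -2.09 on Pax3 replicate 3 and -0.93 to -0.09 on the others. Cell cycle genes were higher, with 17 of 19 positive (median 0.32, adjusted p = 0.000247, and 0.414 with an estimated correlation), such as Mcm4 (0.94), Mcm2 (0.74) and Rrm2 (0.65). Stellate cell markers had a median of 0.38 (adjusted p = 0.0202, and 0.415 with an estimated correlation), with Des at 0.82 and Pdgfrb at 0.57.

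Bile acid, lipoprotein, oxidative phosphorylation and acute phase genes had medians of -0.24, -0.18, -0.18 and -0.21 in Pax3 heterozygotes and passed camera, with adjusted p from 0.0582 to 0.656 with an estimated correlation. After quantile normalization the medians were -0.17, -0.002, -0.03 and -0.07 and none of these 4 lists passed. Camera passed 8 of 27 lists with all arrays and 4 without Pax3 replicate 3. The array weights fit called 18 genes.

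In Lrp6 Cd heterozygotes no gene was called by limma, and 275 genes had an unadjusted p below 0.05, where chance gives 659. As these p-values also use the spread over all 36 arrays, the lower count does not show fewer differences than chance gives. Without CBA replicate 4 and ct replicate 3, 0 genes were called by limma as well. The groups did not overlap in 405 genes, where chance gives 2.86% of the 13188. Lrp6 read 1160 ± 263 against 931 ± 146.5 (log2 0.30 ± 0.34). The smallest p values belonged to A2ml1 (1.85), Hoxa9 (1.51), Mamdc4 (1.22), Surf6 (1.04) and Nob1 (0.68), and to Mrgprf (-1.37), Slc4a1, the erythrocyte anion exchanger (-1.36), Plekhd1os (-1.26), Telo2 (-0.82) and Grb14 (-0.51), all with adjusted p of 1. Other probe sets of Telo2 gave 0.42 and -0.05. Mamdc4, Slc4a1, Plekhd1os and Mrgprf were near background in 1 group (36.4, 20.89, 32.4 and 34.18), and by offset their values ran from 0.80 to 1.56, -1.98 to -0.81, -1.69 to -0.80 and -1.78 to -0.90. Testing all probe sets called 1 gene.

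Cholesterol synthesis genes were lower in Cd heterozygotes in 19 of 20 cases (median -0.52, camera adjusted p = 9.47e-08, and 0.699 with an estimated correlation), with Idi1 at -0.99 ± 0.50, Sqle at -0.97 ± 0.63 and Cyp51 at -0.80 ± 0.40, and 0 of them were below 0.05 even adjusted over the list alone. Clock genes were higher in 14 of 17 cases (median 0.31, adjusted p = 2.07e-05, and 0.115 with an estimated correlation), and Wee1 (0.91 ± 0.28) was higher adjusted over the list alone. Cell cycle genes had a median of -0.24 and stellate cell markers a median of -0.22 (adjusted p = 0.00234 and 0.0165, and 0.856 and 0.699 with an estimated correlation). Camera passed 4 of 27 lists, 7 without heterozygote replicate 2, and 2 without heterozygote replicate 4 or Cd wild type replicate 1. Cd wild type replicate 1 stood apart in its Xist signal, 204 against 4017 to 12560 on the other 7 Cd arrays.

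The folate one-carbon list, which bears on the folic acid response named in the labels, did not move as a group in any line. Its median log2 difference lay between -0.08 in Lp and 0.04 in ct mice, changed sign under median centring in the Pax3 and Apob lines, and the smallest camera adjusted p was 0.791. Of its 24 genes, 1 rose and 1 fell in ct mice and 0 were called by limma in the other 4 lines.

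The contrast of responsive minus resistant lines passed the threshold at 19 genes, 11 higher and 8 lower. Its p-values use the spread between mice within groups. With 2 lines against 3, they do not test a difference between responsive and resistant lines as classes. The 5 with the smallest p were Mff (2.29), Zfp874a (-1.53), Lrba (1.14), Ccdc30 (-1.27) and 1700001C19Rik (1.16), each of which was called in ct mice, where they had log2 differences of -7.03, 3.84, -3.10, 2.39 and -3.95. In the other 4 lines these genes differed by at most 0.40 in either direction, and without probe sets of shared targets the Mff contrast was -0.03. Acute phase genes (median -0.43, adjusted p = 1.14e-07) and Kupffer cell markers (-0.51, adjusted p = 0.000711) were lower in the responsive than in the resistant lines' effects, with adjusted p = 0.413 and 0.593 with an estimated correlation. The ct effect enters both, and without ct replicate 3 and CBA replicate 4, the arrays of doubtful RNA, the medians were -0.29 and -0.15 and the Kupffer list no longer passed camera. Male-biased genes (-0.82), interferon response genes (-0.22) and pancreatic acinar markers (-0.32) passed camera too, with adjusted p = 0.593, 0.774 and 0.16 with an estimated correlation. Lipoprotein (-0.32) and oxidative phosphorylation genes (-0.21) passed camera with the deposited scaling and had adjusted p = 0.522 and 0.43 after quantile normalization, and 0.0016 and 0.000682 after median centring. Neither of these lists passed with an estimated correlation.

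With 5 lines, the ways of choosing 2 of them number 10, so the contrast cannot reach a share below 0.05 among them. The 19 became 58 without ct replicate 1, 32 without CBA replicate 4 and 59 without CBA replicate 4 and ct replicate 3. It became 8 and 10 without Apob replicates 4 and 3, 11 and 9 without Pax3 replicates 2 and 3, 9 without Cd heterozygote replicate 3 or 4, and 11, 10 and 12 without Cd wild type replicates 1, 2 and 3. It was 11 without ct replicate 2 or Lp heterozygote replicate 2 or 4, 10 without Lp wild type replicate 2, and 12 without probe sets of shared targets.

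Across the 5 lines, the mean effect passed the threshold for 15 genes, 9 higher and 6 lower. The smallest p values were those of Mff (-1.31), Zfp874a (0.90), Lrba (-0.69), Gm7969 (0.83) and Tmem51 (0.79), whose largest single effect was in ct mice. Cholesterol synthesis genes were lower on average in 18 of 20 cases (median -0.37, camera adjusted p = 4.45e-11, and 0.483 with an estimated correlation), and 10 were lower adjusted over the list alone. The count was 29 without ct replicate 1 and 23 without CBA replicate 4. No gene was called in 3 or more lines, by limma in each line. Apob and ct mice shared 6 called genes, 1 lower in both and 5 in opposite directions, Gnb1, Kcnmb2, Mdh1, Osbpl8, Rdx and Sh3d19 in all. Chance gives 1.05 higher in both and 1.30 lower in both. For opposite directions no chance value was computed, so the 5 cannot be set against chance.

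The effects differed among the 5 lines at 325 genes, with Mff, 1700001C19Rik, Gm7969, Lrba and Zfp874a first, and at 187 without Apob replicate 3. Between pairs of lines, 503 genes differed between the Apob and ct effects, 498 between Pax3 and ct, 155 between Pax3 and Apob, 113 between ct and Lp, 90 between Cd and ct, and 45 between Apob and Lp. Only 3 differed between Pax3 and Lp and 3 between Cd and Apob, and 0 by limma between Pax3 and Cd and between Cd and Lp. The Pax3 and Apob effects share the B6 control and correlated across genes at r = 0.286. A simulated shared control gave 0.50, a value fixed by the equal spread given to all simulated groups, so it is no yardstick. The covariance of these effects was 0.031, close to the 0.0302 expected from the spread of the 4 B6 arrays. With the 4 B6 arrays split between the Pax3 and Apob effects, r was 0.012 on average over 6 splits, and genes are not independent replicates.

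The control groups differed from one another at 1417 genes. The angiogenin gene had the smallest p and was low in CBA livers alone. The class I histocompatibility gene H2-K1 read 23530 ± 1119 (SD, n = 4) in B6 and 22700 ± 1797 in Lp, against 1546 ± 317.4 in Cd and 1862 ± 392.6 in CBA. Pbld1 and Exosc1 were low in Cd alone, at 36.21 ± 22.48 and 40.25 ± 17.92 against 7996 ± 1008 and 568.7 ± 43.83 in B6. Cyp46a1, a cholesterol hydroxylase, was high in CBA, at 7160 ± 583.2 against 188.4 ± 21.1 in B6. Each of these genes was read by 1 probe set, and strain variants under the probe sets were not tested between control groups. A low signal here therefore need not mean low expression. Against B6, 1019 genes differed in CBA, 513 in Cd and 274 in Lp wild type mice.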

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

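The tests of the female-biased and male-biased lists in Apob mice and of degraded RNA in ct mice were chosen only after the result was seen.

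In 7 of 36 sets of 4 arrays checked for quality, 1 array lay far from the other 3, where chance gives about 1 in 20. CBA replicate 4 had a GAPDH ratio of 52.5, an actin ratio of 31 and a median correlation of 0.859 with its own group, and ct replicate 3 had a GAPDH ratio of 1.72. The median correlation with the own group was 0.949 for Pax3 replicate 3, and the median signal of Lp wild type replicate 4 was 96.8. The correlation of Cd wild type replicate 4 was flagged too, at 0.974 against 0.976 on the other arrays of its group. That gap is close to the rounding of the values and does not mark an outlying array.

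Among 225 sets of 4 signals of named genes, 24 held 1 array far from the other 3, and for 12 of these genes that array was CBA replicate 4. Its signals were 10700 for Gm4951, 4390 for Acsl4, 518 for Nr1h3, 2290 for Lcat, 5610 for Apoe, 25300 for Pygl, 47100 for Slc2a2, 638 for Serpina3n, 12900 for Hpx, 881 for Rpl14, 3630 for Rps14 and 301 for C1qb. Other such signals in this comparison were those of Elobl (133) and Gm4951 (262) on ct replicate 2, Lcat on ct replicate 1 (16900), Klf12 on CBA replicate 1 (4060) and Cyp4a14 on CBA replicate 2 (422). In the Apob comparison they were Sh3d19 (2650) on Apob replicate 1, Sh3d19 (493) and Slc3a1 (378) on B6 replicate 4, and Rdx (5730) on Apob replicate 4. In the other lines they were Telo2 on Cd wild type replicate 4 (268), Coq10b on Lp wild type replicate 2 (330) and Ypel2 on Lp heterozygote replicate 2 (912).

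The effects of the lines differed at 325 genes by an F test, and the contrast of responsive minus resistant lines called 19 genes. For the 325, 1 of 100 regroupings of the arrays gave as many, the real one, with 51 as the highest other, so chance is argued against. For the 19, the 10 ways of choosing 2 lines are too few, and 8 of them gave as many genes, with 184 as the highest other, for the choice of the ct and Lp lines. That is several times the real count and points to the large ct effect as a structure of the samples.

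Probe sets without a single gene symbol, whether unnamed or with several symbols, were outside the comparisons of the report, and 4106 of them passed the filter. Tested in the same way, 4 were called in Apob mice, 94 in ct mice and 3 in Lp mice, and 0 by limma in the Pax3 and Cd lines.

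As lists, female-biased genes had lower and male-biased genes higher values in Apob heterozygotes, though 1 of 10 and 0 of 7 were called over all genes by limma (6 and 0 adjusted over the list alone) and neither list passed with an estimated correlation (adjusted p = 0.0538 and 0.413). Chance values of the shared B6 control arrays are argued against by the comparison of Apob with Pax3 heterozygotes, which leaves B6 out: the median was -1.15 for the female-biased list, with 10 of 10 lower. Male animals are argued against by the Y-linked gene Eif2s3y, whose highest signal on the Apob arrays was 27.6, below the 43.5 found elsewhere. A difference in RNA quality cannot be told apart. The pyruvate carboxylase ratio was lower on every Apob array (2.99 to 5.21) than on every B6 array (5.99 to 26.6, exact permutation p = 0.0286, the smallest these 8 arrays can give). From its slope within other groups it predicted shifts of -0.12 (95% interval -1.02 to 0.79) for the female-biased and 0.04 (-0.91 to 0.99) for the male-biased list, where -1.83 and 0.95 were found. The intervals are too wide to decide, though the GAPDH ratio predicted 0.07 (-0.2 to 0.34) for the female-biased list. An effect of the Apob mutation may be the source, as a hypothesis, and differences in cycle stage or housing were not tested.

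Calls in ct mice were many. Degraded RNA on CBA replicate 4 is argued against as their whole cause, because 315 of 877 genes (35.9%) remained called without that array. Without CBA replicate 4 and ct replicate 3, the arrays of doubtful RNA, 183 of the 877 remained called. Degraded RNA therefore remains open as a cause of the calls that were lost, which were most of them. Leaving out arrays also lowers the precision, so these counts cannot tell how large its part was. Strain variants under single probe sets cannot be told apart from changed expression for all genes. Of 419 called genes with a second probe set, 155 (37%) had it change the same way at an unadjusted p below 0.05 by limma. Second probe sets of other genes passed that threshold in either direction in 19.2% of cases, a margin of 17.8 points. The first share counts a single direction and the second both, so the margin is a low estimate. Without the threshold, 319 of the 419 had the same sign. Called genes were enriched near Grhl3, the mutated gene, in the gene order of GRCm38.p6, with 26 among the nearest 200 tested genes (13%) against 6.53% elsewhere (one-sided Fisher's exact p = 0.000743). A stretch around Grhl3 that differs between the closed colony and CBA mice may therefore carry part of these calls, among them Tmem51, Cela2a, C1qb and Zfp979. Of these, Cela2a and C1qb were not called without CBA replicate 4 and ct replicate 3. Differences between the closed colony and CBA mice remain open, as the design does not separate them from the mutation.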

How the results depend on the processing

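The fits without CBA replicate 4, and without it and ct replicate 3, were chosen only after the result was seen. Where a value moved, the cause was not tested unless stated.

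Offsets at the 5th and 40th percentile and no variance trend left every gene count within 1.5 times its value, with 63 to 77 for Apob and 796 to 937 for ct. The labels give the replicate number no meaning, and 4 of 20 pairs of the same number had r over 0.1 (range -0.141 to 0.203), so the arrays were not taken as paired. In the ct comparison 3 of the 4 pairs did (0.203, 0.201 and 0.107), each best with its own number, as a hint from the data and not from the design, and the pair with ct replicate 3 did not (-0.021). A replicate block gave 83 genes for Apob, 1289 for ct and 5 for Lp.

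Quantile normalization gave 11 genes for Lp and 5 and 2 lists for Pax3 and Lp. Median centring gave 40 genes for Apob (38 of the 71), 9 for responsive minus resistant lines and 215 for differences among lines. No filter gave 2 lists for Cd, and the filter at the 60th percentile 7 genes for Lp. All probe sets gave 1 gene for Cd, 193 for Apob, 7 for Lp, 25 for the mean effect and 522 for differences among lines. Without x_at or s_at probe sets 12 genes were called for responsive minus resistant lines.

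Array weights gave 18 genes for Pax3, 726 for Apob (all 71 among them), 738 for ct (411 of the 877), 151 for Lp, 245 for responsive minus resistant lines, 108 for the mean effect, 1476 for differences among lines and 3944 among controls. With only the arrays compared, Apob had 184 genes (61 of the 71) and ct 38 (38 of the 877).

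Without CBA replicate 4 in any fit, Apob had 211 genes and Lp 20. Without it and ct replicate 3, the counts were 324 for Apob, 236 for ct, 28 for Lp, 59 for responsive minus resistant lines, 28 for the mean effect and 536 for differences among lines.

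With an estimated correlation 0 lists passed for Pax3, Cd, Apob, ct, Lp and responsive minus resistant lines, against 8, 4, 7, 5, 6 and 7 with the preset one. Fry passed 0 for Pax3, Cd and Lp, 1 for Apob, 4 for ct and 2 for responsive minus resistant lines.

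Mff reversed without x_at or s_at probe sets, as another probe set then stood for it: 0.14 in ct mice, -0.03 for responsive minus resistant lines and 0.10 for the mean effect. Vangl2 in Lp mice ran from -0.14 without Lp wild type replicate 1 to 0.58 without Lp wild type replicate 4. Among the other named genes, those of Apob lost the call in 91 of 477 refits and those of ct in 183 of 1188. Ccnd1, Pparg, Prmt1, Rdx and Sult2a2 kept their call in every refit run for them.

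Leaving out 1 array at a time, gene counts ran from 24 (without Apob replicate 3) to 81 (Apob replicate 4) for Apob, 363 (ct replicate 3) to 1438 (ct replicate 1) for ct, 0 (heterozygote replicate 3) to 9 (wild type replicate 1) for Lp, 8 (Apob replicate 4) to 58 (ct replicate 1) for responsive minus resistant lines, 11 (B6 replicate 1) to 29 (ct replicate 1) for the mean effect, 187 (Apob replicate 3) to 486 (CBA replicate 4) for differences among lines and 1114 (B6 replicate 2) to 1857 (CBA replicate 1) among controls. They stayed at 0 by limma for Pax3 and Cd, where 702 and 275 genes had an unadjusted p below 0.05. Lists past camera ran from 4 to 12 for Pax3, 2 to 7 for Cd, 5 to 8 for Apob, 3 to 9 for ct, 5 to 8 for Lp and 6 to 9 for responsive minus resistant lines. Signal over background limits Pax3 and Grhl3, and the size of differences of named genes with 1 group below the signal of the filter: 4 of 11 in the Pax3 line with Pax3 itself, 4 of 11 in Cd, 4 of 22 in Apob, 8 of 57 in ct and 1 of 11 in Lp mice.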

Other observations

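The tests of a male animal and of degraded RNA for the low Xist signal were chosen only after the result was seen.

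The first components of variation held 15.2%, 11.8%, 10.2% and 6.66% of the variance of the 36 arrays. Wild type groups differed more from B6 than most mutants did from their controls: 489 genes were higher and 530 lower in CBA, 203 and 310 in Cd, and 139 and 135 in Lp wild type mice. Pparg read 18.04 ± 5.208 in Lp wild type and 205.3 ± 29.8 in B6 livers, and Nnmt read 1185 ± 720.9 in Cd wild type and 8117 ± 1640 in Lp wild type livers.

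Xist, the transcript that silences 1 X chromosome in females, read 204 on Cd wild type replicate 1 and 4017 to 12560 on the other 7 Cd arrays, and 25.4 against 1098 to 4738 at a second probe set. A male animal is argued against by Eif2s3y, a Y-linked gene, at 4.23 where the highest of the other arrays was 43.5. Degraded RNA is argued against by a GAPDH ratio of 0.733, below the highest of the other Cd arrays, 0.956. A female with 1 X chromosome remains open, as genes that escape silencing had a median of -0.39, with Kdm6a at -0.66, Eif2s3x at -0.48, Ddx3x at -0.30 and Kdm5c at -0.06. No biological explanation beyond these was tested.

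Other splits of the same 8 arrays into 4 and 4 were counted for each line. The real count was the highest of 35 splits in Apob mice (71, highest other 1) and in Lp mice (4, highest other 2). This argues against chance but cannot exclude it, as 1 of 35 is the strongest result these splits can give. In Lp mice the margin was small, and the count was 0 by limma without heterozygote replicate 3. For Pax3 and Cd mice the count says nothing about chance, because with a real count of 0 by limma all 35 splits give at least as many (highest other 1, and 702 and 275 genes at an unadjusted p below 0.05). In ct mice the real count of 877 was the highest of 35, and the split that exchanged ct replicate 1 with CBA replicate 2 gave 772, which points to a structure of the samples other than the group. The Mff signal followed the group on all 8 arrays, at most 58.33 in ct and at least 4958 in CBA mice. For the mean effect (15, highest other 13) and the control groups (1417, highest other 177), 1 of 100 regroupings gave as many, the real one. This argues against chance, though for the mean effect only by a small margin.

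Genes near the mutated gene in the order of GRCm38.p6 were counted for each line. Near Apob 0 of 120 tested genes were called by limma, against 70 elsewhere, and 15% had an unadjusted p below 0.05, against 10.8% elsewhere. As 0.644 calls were expected there at the rate elsewhere, and the odds ratio may be as high as 5.94 (upper 95% limit), a linked segment stays open for this line. Near Vangl2 1 of 200 was called, Apcs, against 3 elsewhere (one-sided Fisher's exact p = 0.0594), which leaves a linked segment open for that gene. Near Pax3 and Lrp6 0 of 200 and 0 of 172 were called by limma. At an unadjusted p below 0.05 were 15 of them (7.5%) near Pax3, against 5.3% elsewhere, and 11 (6.4%) near Lrp6, against 2.03% elsewhere, so a linked segment stays open for these lines too.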
